A study of Homo sapiens with 12 samples.

How the data were processed

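Gene expression was measured in U2OS cells in 3 states, control, quiescent and senescent, with 4 arrays each. The labels state that total RNA was prepared with an RNeasy kit, reverse transcribed from an oligo-dT primer, turned into cRNA with the Cy3 dye and hybridized to a custom one-colour Agilent array of the whole human genome. The labels state a sort for the quiescent cells only.

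The authors read the scans with Agilent Feature Extraction 10.7.3.1, and per the file headers each array file holds the processed signal of each spot as an intensity, after background subtraction and detrending, with no scaling between arrays. The deposited value table holds log2 values, which the values show to be the log2 signal minus about the 75th percentile of each array, without centring per gene. The main values came from the array files, and the deposited values served as an alternative.

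Each array had 52857 spots, of which 1319 were controls and the others held 50238 different probes. Signal was taken as log2 of the processed signal minus the log2 of its 75th percentile over the array. Spots that the scanner software marked as outliers were dropped, 57 to 186 per array, and 0 spots were saturated. Spots of the same probe were averaged. Probes were matched to current gene symbols, 28595 through their accession, 452 through a gene identifier, 2774 through their symbol and 1062 through an older symbol, which gave 19669 genes from 32883 probes. The other 17355 probes had no match and were left out of the comparisons. The array design names probes on an older genome build, and probe sequences were not used here, so positions and cross-hybridization were not checked. Each gene was represented by its brightest probe over all arrays, and 17940 genes whose probe was well above background on at least 4 of the 12 arrays were tested.

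Groups were compared with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). One fit of group means over all 12 arrays gave the 3 comparisons, with empirical Bayes moderation (9 residual and 3.03 prior degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called, in two-sided tests. Where a gene was above background on no array of one group, its fold is a lower bound, computed with the signals of that group raised to the lowest one called above background on the array where they lay below it. Lists of genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 29 pathway lists, and again with an estimated correlation. The preset correlation treats members of a list as nearly independent. A panel of arrest genes and 3 lists of markers of other cell types were described and not counted as pathways. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

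The tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. For each comparison the rule names the 7 largest rises and 7 largest falls among called genes with a proper symbol, no overlap between the groups and a probe above background on all arrays of both. It adds the 3 largest rises and falls by their bounded fold among called genes above background on all arrays of one group and on no array of the other. It then adds up to 4 called members per list described, or up to 2 where 0 passed in limma, and the genes of the panel. Some genes and 1 list that these rules name are not reported here.

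The alternatives were normexp background correction with an offset of 50 on the raw mean and background signals, quantile and median scaling, the deposited table, no filter or a filter requiring all 12 arrays, the mean of all probes of a gene, outlier spots kept, signals floored at the lowest 5 percent point, slide as a fixed or random block, each slide alone with the spread pooled over all arrays, replicate number as a block, only the 2 groups compared, array weights, an intensity trend, an adjusted p under 0.01, a fold of at least 2, each array left out in turn, fry in place of camera, and separate controls for each arrest. Within slide 2 a single quiescent and a single senescent array were assumed to vary like the other groups. Added after the data were seen were the removal of Quiescent 1 and Quiescent 3 and the inclusion of unmatched transcripts.

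The gene and list tests were tested on simulated data, in which 2 of 2 lists moved by 2-fold and 0 of 27 others were called in camera. Genes varied independently in these data, so they cannot show how often lists of genes that move together pass by chance. For each comparison all 35 ways to split its 8 arrays into groups of 4 were tested, and 100 random splits of the 12 arrays for the changes shared by both arrests. Within the groups, no array was found to be a copy of another, since the closest pair of one group had a median absolute log2 difference of 0.33, against 0.14 between spots of one probe on one array. Dixon's ratio was used to find arrays far from the other 3 of their state. The number of arrays limits the precision, and the spread between arrays is that of replicates whose origin the labels do not state.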

Results

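RNA of U2OS cells, an established human osteosarcoma line, was measured on 12 one-colour microarrays, 4 per state. Control cells grew in 10% serum. Quiescent cells were kept in 0.1% serum for 96 h, after which cells in G0 were sorted by flow cytometry. Senescent cells received 1 µM doxorubicin, a drug that breaks DNA, for 2 h and then fresh medium for 8 days, with no serum level stated. The labels do not say whether replicates were separate cultures. Each array carried 50238 different probes besides its controls, of which 68.9% to 81.8% were above background. The 75th percentile of the signal ranged from 415 to 1271 intensity units, and the number of arrays limits the precision. After scaling, 17940 genes were tested.

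The arrays separated by state. The first principal component held 40.4% of the variance, with control arrays at -102 to -56.0, quiescent arrays at -20.7 to 15.3 and senescent arrays at 67.4 to 104. The second component held 20% of the variance and lay at -96.3 on Quiescent 1, -27.1 on Quiescent 2, -108 on Quiescent 3 and -13.3 on Quiescent 4. Quiescent 1 and Quiescent 3 also had the lowest 75th percentile signals, 470 and 415. Correlations across genes between arrays of one group were 0.951 to 0.977 for control, 0.938 to 0.973 for quiescent and 0.967 to 0.988 for senescent cells, and genes are not independent replicates. The arrays lay on 2 slides, and 673 genes differed between the slides in limma with group in the fit. Slide 1 held 2 control, 3 quiescent and 3 senescent arrays, and slide 2 held 2 control, 1 quiescent and 1 senescent array. Control 1 was scanned in a session apart from the rest, so that session cannot be compared with the others.

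**Figure D1:**
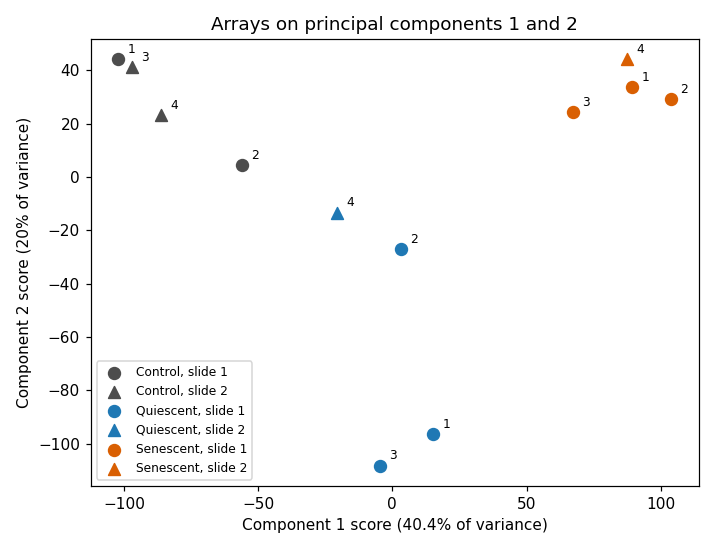
Each point is 1 array, placed by its scores on principal components 1 and 2 of the 17940 tested genes, coloured by state and shaped by slide. Control arrays lie at -102 to -56.0 on component 1 and senescent arrays at 67.4 to 104.

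Changes are log2 differences of group means from limma, over 4 and 4 arrays, given ± the standard error. Each gene said to rise or fall had a Benjamini-Hochberg adjusted p below the threshold over all 17940 genes. A list's count is followed in round brackets by the count adjusted over the list alone, and its adjusted p by that with an estimated correlation. Its median change is followed in square brackets by the median with slide as a block, within slide 1 and within slide 2. Comparisons with quiescent cells have a further value without Quiescent 1 and Quiescent 3, an alternative added after the data were seen. The letters ns mark a setting under which the list no longer passed. For senescent against quiescent cells, slide 2 had 1 array of each, so its values carry no test. The 5340 probes above background on no array had median changes of 0.72 in quiescent and 0.56 in senescent cells against control, so dim probes lay higher in both arrests. Values given for other settings and for single arrays left out are adjusted p unless named as a median or a change.

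The first comparison asked how serum-starved, sorted G0 cells differed from proliferating cells. The quiescent cells carried far less RNA of the division machinery. MKI67, the proliferation antigen Ki-67, fell by 4.53 ± 0.59 on the log2 scale (n = 4 and 4 arrays), and 38 of 39 measured mitosis genes fell, MKI67 among them. Of 31 immediate-early genes 19 rose, led by the AP-1 subunit FOS (5.0 ± 0.54) and the zinc-finger factor EGR2 (4.26 ± 0.80). The stress cytokine GDF15 rose (4.74 ± 0.80), as did 12 of 23 FOXO targets, such as FBXO32, a ubiquitin ligase of muscle atrophy (3.60 ± 0.39). Large rises were also seen for PKIB, an inhibitor of protein kinase A (4.82 ± 0.54), CNIH3, which binds AMPA receptors (4.45 ± 0.93), the nuclear body protein SP140 (4.29 ± 0.64) and the secreted trypsin inhibitor SPINK1 (4.27 ± 0.45). The largest falls were those of the linker histone H1-1 (-6.10 ± 0.56), the centromere chaperone HJURP (-4.94 ± 0.35), the carbonic anhydrase CA12 (-4.82 ± 0.55), the bradykinin receptor BDKRB1 (-4.65 ± 0.48), the spindle protein CKAP2L (-4.61 ± 0.44), the matrix metalloprotease MMP3 (-4.56 ± 0.78) and the ribonucleotide reductase subunit RRM2 (-4.55 ± 0.55). The named genes had adjusted p of at most 0.00644. Above background on all 4 quiescent arrays and on 0 of 4 control arrays were EGR4 (at least 51.7-fold), HTN1 (at least 20.8-fold) and MGAT4C (at least 20.7-fold), each higher. The opposite held for MRAP2 (at least 5.99-fold), FLRT1 (at least 5.02-fold) and CLEC1B (at least 4.85-fold), each lower. The bounded genes had adjusted p of 5.69e-05 to 0.00201. HTN1 and HTN3 are near copies whose signals were not separated, and the bound for MRAP2 is for its brightest probe, since another of its probes was above background on 1 quiescent array. With 1 array left out, values moved for EGR2 (changes 4.86 without Quiescent 3, 3.61 without Quiescent 4), GDF15 (changes 3.95 without Quiescent 1, 5.37 without Quiescent 4) and PKIB (change 5.47 without Control 4). Also moved were CNIH3 (changes 3.35 without Control 3, 5.35 without Control 4) and MMP3 (change -5.37 without Quiescent 3). Also moved, but unbounded over dark arrays, were EGR4 (change 7.61 without Quiescent 3), HTN1 (change 4.83 without Quiescent 1), MGAT4C (changes 6.02 without Quiescent 2, 4.48 without Quiescent 3, 6.12 without Quiescent 4) and CLEC1B (change -4.15 without Control 4).

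Genes of the cell cycle fell as groups. Of DNA replication genes, 38 of 40 fell (38 and 1 higher), among them RRM2 (-4.55 ± 0.55), CLSPN (-4.36 ± 0.59) and MCM10 (-3.75 ± 0.36). The list median was -1.79 [-1.77, -1.99, -1.42, -1.80], with adjusted p = 2.61e-31 (0.0211 estimated). Of mitosis genes, 38 of 39 fell (38), including the kinase AURKB (-4.44 ± 0.53) and the topoisomerase TOP2A (-4.23 ± 0.56). Over the list the median was -3.40 [-3.23, -3.72, -2.09, -2.77], with adjusted p = 8.36e-37 (0.0968 estimated). In homologous recombination, 17 of 20 fell (18), with BRIP1 (-4.18 ± 0.39), RAD54L (-3.88 ± 0.36) and EXO1 (-3.49 ± 0.40). Its median change was -2.65 [-2.62, -2.77, -2.12, -2.32], with adjusted p = 3.62e-20 (0.0153 estimated). For chromatin and lamina genes, 21 of 30 fell (23), led by the lamin LMNB1 (-3.74 ± 0.50) and the condensin subunits NCAPG (-3.52 ± 0.36) and NCAPH (-3.40 ± 0.36). Their median was -1.63 [-1.51, -1.67, -1.15, -1.37], with adjusted p = 4.05e-17 (0.0268 estimated). Among replication-dependent histones, 9 of 33 fell (10), with the H4 genes H4C3 (-2.64 ± 0.52) and H4C2 (-2.57 ± 0.35). Their median was -0.27 [-0.21, -0.38, 0.10 ns, 0.20 ns], with adjusted p = 2.08e-04 (0.445 estimated). All histone values cover only RNA with a poly(A) tail (oligo-dT primer). Of extracellular matrix genes, 7 of 27 fell (7), including the collagen COL1A1 (-2.97 ± 0.75) and thrombospondin THBS1 (-2.59 ± 0.45). Their median was -0.60 [-0.61, -0.53, -0.25 ns, -0.33 ns], with adjusted p = 0.00187 (0.410 estimated). In the proteasome, 3 of 31 fell (2), led by PSMD2 (-1.37 ± 0.30). The median of the list was -0.22 [-0.25, -0.27, -0.13 ns, -0.25], with adjusted p = 0.00569 (0.503 estimated). For the genes named, adjusted p was at most 0.0166. Quiescent 4 lay apart in 3 of these lists. Relative to the mean of the control arrays, medians on Quiescent 1 to 4 were -3.94, -3.57, -3.90 and -1.98 for mitosis, -1.61, -1.64, -1.97 and -0.97 for chromatin and lamina and -2.10, -1.98, -1.98 and -1.48 for DNA replication. Other settings changed histones (median -0.09 with array weights), extracellular matrix (median -0.28 with normexp) and proteasome (median -0.35 with quantile scaling). Leaving out 1 array moved CLSPN (change -3.64 without Quiescent 1), histones (medians -0.43 without Control 1, -0.12 without Quiescent 1, -0.61 without Quiescent 2, -0.14 without Quiescent 3, -0.51 without Control 3, 0.01 without Control 4, -0.52 without Quiescent 4) and proteasome (median -0.11 without Control 2).

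Other groups rose. Among immediate-early genes, 19 of 31 rose (19), including EGR1 (4.12 ± 0.49) and NR4A2 (3.02 ± 0.34). The list median was 1.15 [1.24, 0.87, 1.64, 1.40], with adjusted p = 2.52e-07 (0.137 estimated). Of FOXO targets, 12 of 23 rose and 1 fell (13 and 1), among them KLHL24 (2.63 ± 0.26), PDK4 (2.44 ± 0.48) and BCL6 (2.25 ± 0.35). The list had a median of 1.06 [0.99, 0.91, 1.12, 1.29], with adjusted p = 3.41e-05 (0.0968 estimated). Among genes of the senescence-associated secretory phenotype, 10 of 34 rose and 1 fell (11 and 1), with CXCL8 (4.15 ± 1.06) and IL6 (3.35 ± 0.48) up and MMP3 down. The list median was 0.60 [0.66, 0.68, 0.60, 0.75], with adjusted p = 0.0176 (0.421 estimated). For NF-kB targets, 13 of 21 rose and 1 fell (13 and 1), including the cytokines LTB (3.38 ± 0.67) and CCL20 (3.21 ± 0.50). The list median was 1.5 [1.54, 1.55, 1.34, 1.86], with adjusted p = 6.07e-06 (0.0645 estimated). Of autophagy genes, 9 of 21 rose (11 and 1 lower), led by WIPI1 (2.86 ± 0.37), OPTN (2.03 ± 0.28) and DRAM1 (1.90 ± 0.33). Its median change was 0.69 [0.71, 0.71, 0.52, 0.61], with adjusted p = 0.00151 (0.120 estimated). Adjusted p was at most 0.0176 for these named genes. Processing mattered for secretory phenotype (0.0542 with no filter). Single arrays decided calls or values of secretory phenotype (0.0501 without Quiescent 4) and CXCL8 (change 4.93 without Quiescent 2, change 2.87 without Quiescent 3, 0.0521 without Control 3).

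Ribosomal protein genes rose on the quiescent arrays, where 23 of 48 rose (40), with RPL22 (1.23 ± 0.27), for which 1 of 3 other probes went the opposite way (-0.21). The list median was 0.84 [0.77, 0.89, 0.47, 0.41], with adjusted p = 4.66e-10 (0.421 estimated). Relative to the mean of the control arrays, the median of this list was 1.25, 0.42, 1.23 and 0.36 on Quiescent 1 to 4, against -0.21, 0.35, -0.23 and 0.12 on Control 1 to 4. Without Quiescent 1 and Quiescent 3, 0 of the 23 called members passed in limma, with fewer arrays, and 12 of the 48 were higher at an unadjusted p under 0.05. Near-identical pseudogene copies of these genes were not separated. In the integrated stress response, 7 of 25 rose and 3 fell (8 and 3), led by the transcription factor DDIT3 (4.04 ± 0.64). Their median change was 0.60 [0.58 ns, 1.04, -0.29 ns, 0.05 ns], with adjusted p = 0.0493 (0.675 estimated). In the unfolded protein response, 4 of 16 rose (4), with DNAJB9 (2.57 ± 0.29) and HERPUD1 (2.49 ± 0.46). The members had a median of 0.48 [0.32 ns, 0.65, 0.03 ns, -0.18 ns], with adjusted p = 0.0246 (0.586 estimated). The largest adjusted p among the named genes was 0.00775. Outcomes also turned on the setting for ribosomal proteins (median 0.35 with quantile scaling), integrated stress response (0.186 with normexp, median 0.36 and 0.0568 with quantile scaling, 0.0710 with no filter, 0.0514 with the mean of probes, 0.0770 with the replicate block, 0.0643 with only 2 groups fitted, median 0.27 with array weights) and unfolded protein response (0.0950 with normexp, median 0.27 with array weights). Calls or values that turned on 1 array were those of integrated stress response (0.0761 without Control 1, 0.143 without Control 2, 0.111 without Quiescent 1, 0.230 without Quiescent 3, 0.0516 without Senescent 1, 0.0620 without Senescent 3, 0.0663 without Control 3, 0.0549 without Senescent 4), DDIT3 (change 4.67 without Quiescent 4) and unfolded protein response (0.0505 without Control 2, 0.0816 without Quiescent 1, 0.173 without Quiescent 3, median 0.76 without Quiescent 4).

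In the panel of arrest genes, the rises were GDF15 (4.74 ± 0.80), CXCL8 (4.15 ± 1.06), IL6 (3.35 ± 0.48), CDKN1C (2.02 ± 0.29) and MYC (1.87 ± 0.31). The falls were MKI67 (-4.53 ± 0.59), LMNB1 (-3.74 ± 0.50), CCNB1 (-2.70 ± 0.40), E2F1 (-2.56 ± 0.29), CCNE2 (-2.06 ± 0.57), RBL1 (-1.77 ± 0.21) and HMGB2 (-1.20 ± 0.31). These calls had adjusted p of at most 0.0251. Not passing, with adjusted p, were IL1A (2.18 ± 0.84, 0.0883), CCND1 (-1.10 ± 0.49, 0.131), RB1 (0.63 ± 0.28, 0.136), RBL2 (0.44 ± 0.21, 0.158) and GLB1 (0.67 ± 0.32, 0.163). Nor did CDKN2B (-1.30 ± 0.77, 0.241), CDKN1B (-0.30 ± 0.32, 0.516), MDM2 (0.25 ± 0.34, 0.626), CDKN1A (0.28 ± 0.40, 0.641) and CDKN2A (-0.13 ± 0.62, 0.897) pass. GDF15 and CXCL8 encode secreted factors of stress, CDKN1C a CDK inhibitor and E2F1 a factor of S-phase entry. CDKN1A encodes the CDK inhibitor p21, and CDKN2A, from which p16 is made, was above background on 4 of 4 control, 4 of 4 quiescent, 4 of 4 senescent arrays. With 1 array left out, calls or values moved for CCNE2 (0.0658 without Quiescent 1, 0.0629 without Quiescent 3, 0.0708 without Control 3, 0.0646 without Control 4), HMGB2 (0.0532 without Quiescent 1) and IL1A (change 1.05 and 0.0497 without Quiescent 3). Also moved by 1 array were CDKN2B (change -0.53 without Control 4).

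A total of 13 lists did not pass, with adjusted p of 0.0678 to 0.821. Each is given with its genes higher and lower of those tested, and the counts adjusted over the list alone are equal where not given. These were heat shock (0 and 1 of 14, median -0.19), lysosome (8 and 0 of 33, median 0.44), fatty acid synthesis (1 and 2 of 16, median -0.22), glycolysis and hypoxia (2 and 4 of 26, 2 and 5 over the list alone, median -0.18) and ribosome biogenesis (0 and 1 of 32, median -0.19). Next came oxidative phosphorylation (0 and 3 of 36, 0 and 1 over the list alone, median -0.02), interferon response (4 and 0 of 30, median 0.37), BCL2 family (4 and 0 of 16, median 0.18), cholesterol synthesis (6 and 2 of 24, 9 and 3 over the list alone, median 0.24) and osteoblast lineage (0 and 1 of 9, median -0.29). The remainder were CDK inhibitors (1 and 1 of 7, median -0.30), NRF2 targets (3 and 1 of 16, 3 and 2 over the list alone, median -0.05) and SRF and YAP cytoskeletal targets (5 and 1 of 24, 5 and 2 over the list alone, median 0.10). Passing with slide as a block, with medians and adjusted p at the preset correlation, were ribosome biogenesis (-0.19, 0.0495). Within slide 1 these were heat shock (-0.36, 0.0153), fatty acid synthesis (-0.32, 0.0330) and oxidative phosphorylation (-0.17, 0.0298). Within slide 2 these were interferon response (0.89, 5.05e-05) and ribosome biogenesis (-0.34, 0.0438). Without Quiescent 1 and Quiescent 3 these were interferon response (0.80, 0.00111) and ribosome biogenesis (-0.29, 0.00228). Called genes of all these lists included PMAIP1 (3.15 ± 0.27), STARD4 (2.06 ± 0.27), CA9 (-2.62 ± 0.34) and RIGI (1.99 ± 0.33), adjusted p at most 0.00181. Markers of other cell types were haematopoietic markers (1 higher and 0 lower of 13, 0 and 0 over the list alone, 2 and 0 in limma at an unadjusted p under 0.05, median 0.27, adjusted p = 0.534), epithelial markers (1 higher and 1 lower of 12, 0 and 1 over the list alone, median 0.51, adjusted p = 0.534) and endothelial markers (1 higher and 0 lower of 7, 1 and 0 over the list alone, median 0.13, adjusted p = 0.534). The arrest panel itself had a median of 0.15, a mean of -0.02 and a test pointing down. Other settings changed heat shock (0.00668 with normexp, 0.0131 with quantile scaling, 0.0484 with median scaling, 0.0138 with the mean of probes), fatty acid synthesis (0.0466 with normexp) and ribosome biogenesis (0.0122 with normexp). Further ones were oxidative phosphorylation (0.00774 with normexp, 0.0403 with quantile scaling). Leaving out 1 array moved calls or values of heat shock (0.0414 without Quiescent 2, 0.0319 without Control 4, 0.0401 without Quiescent 4), lysosome (0.0192 without Control 1, 0.0374 without Quiescent 4) and ribosome biogenesis (0.0168 without Quiescent 3). The same was true of interferon response (0.0401 without Quiescent 1).

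In all, 2028 genes were higher and 1561 lower in quiescent cells, 3589 of 17940 by limma. Of these, 1455 and 1156 differed at least 2-fold, and 91 and 132 at least 8-fold. The groups did not overlap for 22.7% of tested genes, where chance gives 2.86%. With slide as a block the counts were 2047 and 1609, within slide 1 they were 803 and 889, and within slide 2, with 1 quiescent array, 48 and 71. Of the 29 lists 16 passed, 3 of them also with an estimated correlation, and 3 of the 35 splits of the 8 arrays, the real one included, shifted as many. By fry 14 passed, not histones (0.0895), integrated stress response (0.116), proteasome (0.0895) or unfolded protein response (0.0690), and newly lysosome (0.0200) and BCL2 family (0.00135). The median over all genes was 0.15, or 0.07 with median scaling, 0.08 with quantile and 0.28 with normexp, and the share of calls that were higher was 56.5%, or 48.5%, 52.2% and 66.0%. Without Quiescent 1 and Quiescent 3 the counts were 1283 and 1039, without Quiescent 1 alone 1264 genes were higher, and without Control 3 alone 1273. Of the 78 genes named for this comparison 68 were called. With slide as a block 68 of these were called and 68 kept their direction, within slide 1 59 and 68, and within slide 2 20 and 68.

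The next comparison set cells 8 days after doxorubicin against proliferating cells. Of the mitosis genes 38 of 39 fell, and of the genes of the senescence-associated secretory phenotype 18 of 34 rose and 1 fell. The mitotic kinesin KIF20A fell (-5.37 ± 0.76, n = 4 and 4 arrays) with the mitotic kinase AURKB (-4.73 ± 0.53) and lamin B1, a nuclear envelope protein encoded by LMNB1 (-4.82 ± 0.50). The monocyte chemokine CCL2 rose (6.81 ± 0.37), as did the growth factors of the EGF family EREG (6.10 ± 0.74) and AREG (5.76 ± 0.51). The histone gene H4C3 fell (-4.83 ± 0.52). The largest rises were those of the trypsin inhibitor SPINK1 (8.52 ± 0.45), the protease family member PRSS35 (8.21 ± 0.48), the long non-coding RNA DIRC3 (8.04 ± 0.54), the testis gene TSGA10 (7.80 ± 0.45), beta-defensin 3 (7.53 ± 1.12 for DEFB103B, not separated from its near copy DEFB103A), the membrane traffic protein MAL2 (7.42 ± 0.47) and the long non-coding RNA UCA1 (7.0 ± 0.85). Besides those named, the largest falls were those of the chemokine CXCL14 (-6.81 ± 0.98), the inhibitor of differentiation ID3 (-6.07 ± 0.40) and the dehydrogenase DHRS2 (-5.80 ± 0.77). The named genes had adjusted p of at most 3.61e-04. Above background on all 4 senescent arrays and on 0 of 4 control arrays were TRIM63 (at least 231-fold), DENND2D (at least 225-fold) and HTN1 (at least 174-fold), each higher. The opposite held for SKIDA1 (at least 12.3-fold), HTR2A (at least 10.1-fold) and HAUS5 (at least 9.81-fold), each lower. TRIM63 encodes a ubiquitin ligase of muscle, HTR2A a serotonin receptor and HAUS5 a spindle protein. The bounded genes had adjusted p of 1.31e-06 to 0.00191. Single arrays moved EREG (change 6.83 without Senescent 3), CXCL14 (change -6.19 without Control 4) and DENND2D (change 10.06 without Senescent 3, unbounded over dark arrays).

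Cell cycle groups fell here too. Of DNA replication genes, 37 of 40 fell (39), with RRM2 (-4.51 ± 0.55), CDT1 (-3.26 ± 0.35) and POLE2 (-3.05 ± 0.76). The median of the list was -2.06 [-2.03, -1.95, -2.23], with adjusted p = 5.68e-25 (0.0287 estimated). Of mitosis genes, 38 of 39 fell (38), including MKI67 (-4.67 ± 0.59) and PLK1 (-4.47 ± 0.42). Their median was -3.55 [-3.38, -3.38, -3.76], with adjusted p = 2.51e-30 (0.133 estimated). In homologous recombination, 18 of 20 fell (18), with the nuclease EXO1 (-3.67 ± 0.40) and the helicase BLM (-3.21 ± 0.27). The list had a median of -2.09 [-1.99, -2.10, -2.19], with adjusted p = 1.15e-13 (0.0287 estimated). For chromatin and lamina genes, 26 of 30 fell (27), with LMNB1 and the condensin subunits NCAPD2 (-3.69 ± 0.31) and NCAPG (-3.18 ± 0.36). The list median was -2.12 [-2.05, -2.13, -2.17], with adjusted p = 4.58e-19 (0.0287 estimated). Among replication-dependent histones, 10 of 33 fell (9), with H4C2 (-3.30 ± 0.35) after H4C3. Their median was -0.75 [-0.68, -0.58, -0.57], with adjusted p = 5.23e-04 (0.408 estimated). Of extracellular matrix genes, 8 of 27 fell (8), with COL1A1 (-4.24 ± 0.75) and COL5A2 (-2.38 ± 0.37, other probes -0.33 and -0.18). Their median was -0.77 [-0.75, -0.71, -0.51], with adjusted p = 5.23e-04 (0.301 estimated). For the genes named, adjusted p was at most 0.00884.

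Metabolic and protein-handling groups also fell at the preset correlation. Of cholesterol synthesis genes, 2 of 24 rose and 8 fell (2 and 9), with ACAT2 (-1.71 ± 0.26), EBP (-1.48 ± 0.24) and INSIG1 (-1.31 ± 0.19). The list median was -0.45 [-0.47, -0.62, -0.50], with adjusted p = 0.00489 (0.394 estimated). Of fatty acid synthesis genes, 1 of 16 rose and 5 fell (1 and 5), with the synthase FASN (-1.51 ± 0.41) and the desaturase FADS2 (-1.46 ± 0.28). Their median change was -0.40 [-0.43, -0.69, -0.49], with adjusted p = 0.0104 (0.204 estimated). In ribosome biogenesis, 9 of 32 fell (9), with UBTF (-1.86 ± 0.29) and FBL (-1.35 ± 0.25). The list median was -0.42 [-0.49, -0.47, -0.51], with adjusted p = 3.91e-04 (0.394 estimated). In the proteasome, 13 of 31 fell (13), with PSMC3 (-1.26 ± 0.23) and PSMD13 (-1.09 ± 0.34). The median of the list was -0.48 [-0.50, -0.54, -0.44], with adjusted p = 5.74e-05 (0.357 estimated). In oxidative phosphorylation, 9 of 36 fell (1), with the ATP synthase subunit ATP5F1B (-1.35 ± 0.27). The list median was -0.29 [-0.37, -0.46, -0.27], with adjusted p = 6.60e-04 (0.394 estimated). Adjusted p was at most 0.0259 for these named genes. Processing mattered for oxidative phosphorylation (median -0.49 with median scaling). Calls or values that turned on 1 array were those of PSMD13 (0.0548 without Control 1, 0.0638 without Senescent 1, 0.0716 without Senescent 2, 0.0766 without Control 3, 0.0769 without Senescent 4) and oxidative phosphorylation (median -0.16 without Control 2).

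Secretory, lysosomal and stress groups rose at the preset correlation. Among genes of the secretory phenotype, 18 of 34 rose and 1 fell (20 and 1), led by CCL2, EREG and GDF15 (5.96 ± 0.80). The list had a median of 1.56 [1.58, 1.74, 1.32], with adjusted p = 1.95e-05 (0.151 estimated). For NF-kB targets, 17 of 21 rose (17), with CCL2, LTB (5.88 ± 0.67), CXCL8 (5.33 ± 1.06) and TNFAIP3 (4.04 ± 0.43). The list median was 1.60 [1.54, 1.87, 1.61], with adjusted p = 1.51e-07 (0.0287 estimated). Of lysosome genes, 24 of 33 rose (27), with SGSH (2.07 ± 0.36), NPC1 (2.06 ± 0.22) and PSAP (2.01 ± 0.30). The list median was 1.11 [1.07, 1.01, 1.15], with adjusted p = 2.62e-07 (0.133 estimated). Of autophagy genes, 9 of 21 rose (9), with DRAM1 (3.58 ± 0.33) and WIPI1 (2.12 ± 0.37). Its median change was 0.68 [0.62, 0.27 ns, 0.98], with adjusted p = 0.0284 (0.301 estimated). Of FOXO targets, 10 of 23 rose and 1 fell (13 and 2), with BCL6 (3.53 ± 0.35) and FBXO32 (2.98 ± 0.39). The list median was 0.76 [0.81, 0.95, 0.61], with adjusted p = 0.0150 (0.307 estimated). Of immediate-early genes, 13 of 31 rose and 4 fell (13 and 5), with FOS (2.70 ± 0.54), DUSP5 (2.43 ± 0.55) and IER3 (2.27 ± 0.34). Their median change was 0.92 [0.94, 1.15 ns, 0.89], with adjusted p = 0.0381 (0.427 estimated). The largest adjusted p among the named genes was 0.00539. Outcomes also turned on the setting for secretory phenotype (median 1.01 with normexp), autophagy (0.0513 with median scaling, 0.0680 with the mean of probes) and immediate-early (0.0810 with normexp, 0.0555 with no filter, 0.0524 with the mean of probes). With 1 array left out, calls or values moved for immediate-early (0.0880 without Control 2, 0.0529 without Senescent 3, 0.0679 without Control 3).

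In the panel of arrest genes, the rises were GDF15 (5.96 ± 0.80), CXCL8 (5.33 ± 1.06), IL1A (4.41 ± 0.84), IL6 (2.55 ± 0.48), MDM2 (2.06 ± 0.34) and CDKN1A (1.18 ± 0.40). The falls were LMNB1 (-4.82 ± 0.50), MKI67 (-4.67 ± 0.59), CCNB1 (-3.41 ± 0.40), HMGB2 (-2.78 ± 0.31), RBL1 (-2.56 ± 0.21), CDKN2B (-2.44 ± 0.77), CCNE2 (-2.35 ± 0.57) and E2F1 (-1.80 ± 0.29). These calls had adjusted p of at most 0.0389. Not passing, with adjusted p, were RBL2 (0.58 ± 0.21, 0.0527), GLB1 (0.79 ± 0.32, 0.0808), CDKN1B (-0.72 ± 0.32, 0.103) and CDKN1C (0.61 ± 0.29, 0.131). Nor did MYC (0.42 ± 0.31, 0.317), CCND1 (-0.62 ± 0.49, 0.344), CDKN2A (0.60 ± 0.62, 0.474) and RB1 (0.17 ± 0.28, 0.673) pass. MDM2 encodes a ubiquitin ligase, HMGB2 a chromatin protein of dividing cells and GLB1 the lysosomal beta-galactosidase. Leaving out 1 array moved calls or values of CDKN1A (0.102 without Control 1, 0.0906 without Control 2, 0.0741 without Senescent 1, 0.0647 without Senescent 2, 0.0811 without Senescent 3, 0.0613 without Control 4, 0.0779 without Senescent 4), CDKN2B (0.0527 without Senescent 1, 0.0626 without Senescent 3, change -1.67 and 0.0598 without Control 4, 0.0706 without Senescent 4) and RBL2 (0.0421 without Quiescent 1, 0.0348 without Quiescent 2, 0.0393 without Senescent 3). The same was true of GLB1 (0.0414 without Control 1, 0.0264 without Control 2) and CDKN2A (change 0.03 without Senescent 4).

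A total of 11 lists did not pass, with adjusted p of 0.0507 to 0.795. These were osteoblast lineage (1 and 5 of 9, median -0.84), heat shock (1 and 3 of 14, median -0.19), interferon response (7 and 1 of 30, 7 and 0 over the list alone, median 0.60), NRF2 targets (2 and 5 of 16, median -0.33) and glycolysis and hypoxia (5 and 7 of 26, 5 and 8 over the list alone, median -0.23). The remainder were CDK inhibitors (1 and 2 of 7, median 0.04), BCL2 family (4 and 2 of 16, 5 and 2 over the list alone, median 0.17), SRF and YAP cytoskeletal targets (6 and 2 of 24, median 0.14), unfolded protein response (6 and 1 of 16, median 0.08), ribosomal proteins (0 and 0 of 48, 1 and 0 in limma at an unadjusted p under 0.05, median 0.09) and integrated stress response (6 and 4 of 25, 7 and 4 over the list alone, median 0.43). Passing within slide 1, with medians and adjusted p at the preset correlation, were heat shock (-0.25, 0.0465). Within slide 2 these were osteoblast lineage (-1.02, 0.0270). Among the interferon response genes, the RNA sensor RIGI (4.29 ± 0.33) and IFIT2 (4.27 ± 0.54) rose. In other lists PMAIP1 (3.02 ± 0.27), DDIT3 (3.54 ± 0.64), AKR1B10 (3.85 ± 0.54) and ANGPTL4 (3.59 ± 0.95) rose and the osteoblast factor MSX2 (-2.73 ± 0.41) fell. The named genes had adjusted p of at most 0.0125. Signs differed within lists whose test pointed down: the median and mean were 0.04 and -0.56 for CDK inhibitors, 0.09 and 0.07 for ribosomal proteins, -0.23 and 0.01 for glycolysis and hypoxia, and 0.16 and -0.10 for the arrest panel. The ribosomal protein gene with the largest change was RPL22 (0.58 ± 0.27, adjusted p = 0.114). Markers of other cell types were haematopoietic markers (2 higher and 0 lower of 13, 2 and 0 over the list alone, median 0.88, adjusted p = 0.207), epithelial markers (2 higher and 0 lower of 12, 2 and 0 over the list alone, median 0.69, adjusted p = 0.413) and endothelial markers (2 higher and 0 lower of 7, 2 and 0 over the list alone, median 0.81, adjusted p = 0.212). Other settings changed osteoblast lineage (0.0492 with the filter on all arrays), heat shock (0.0365 with normexp) and NRF2 targets (0.0436 with the filter on all arrays). Single arrays decided calls or values of osteoblast lineage (0.0478 without Control 1, 0.0430 without Control 2, 0.0496 without Senescent 1, 0.0352 without Senescent 2, 0.04997 without Quiescent 4), heat shock (0.0447 without Control 4) and ANGPTL4 (change 2.83 without Control 3).

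In all, 3566 genes were higher and 2434 lower in senescent cells, 6000 of 17940 by limma. Of these, 2846 and 1676 differed at least 2-fold, and 497 and 174 at least 8-fold. The groups did not overlap for 37.5% of tested genes, where chance gives 2.86%. By the brightest probe, 153 called genes were above background on all 4 senescent arrays and no control array, and 38 the reverse (6 with normexp, 41 and 42 with the other scalings), and 145 of the 153 were dark on the control arrays by every probe. With slide as a block the counts were 3806 and 2446, within slide 1 they were 2049 and 1390, and within slide 2, with 1 senescent array, 1354 and 883. Of the 29 lists 18 passed, 4 of them also with an estimated correlation, and 1 of the 35 splits of the 8 arrays, the real one, shifted as many. By fry 21 passed, not histones (0.0554), and newly interferon response (0.0265), BCL2 family (5.79e-04), osteoblast lineage (0.0186) and SRF and YAP targets (0.0247). The median over all genes was 0.21, or 0.01 with median scaling, 0.12 with quantile and 0.25 with normexp, and the share of calls that were higher was 59.4%, or 46.2%, 55.2% and 62.1%. Of the 95 genes named for this comparison 86 were called. With slide as a block 86 of these were called and 86 kept their direction, within slide 1 75 and 86, and within slide 2 68 and 86.

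The last comparison set senescent directly against quiescent cells, the contrast in the series title. Of the genes of the secretory phenotype 10 of 34 were higher in senescence and 2 lower. The metalloproteases MMP3 (6.69 ± 0.78, n = 4 and 4 arrays) and MMP1 (3.54 ± 0.47), the plasminogen activator PLAT (4.42 ± 0.49) and CCL2 (3.70 ± 0.37) rose. Of 31 immediate-early genes 11 were lower and 3 higher, and the lower ones included the MAP kinase phosphatase DUSP2 (-4.13 ± 0.41) and FOS (-2.30 ± 0.54). Of 24 cholesterol synthesis genes 9 were lower and 1 higher, and the lower ones included INSIG1, which holds back the SREBP pathway (-2.02 ± 0.19), and IDI1 (-1.79 ± 0.19). The other largest rises were PRSS35 (8.48 ± 0.48), the kallikrein inhibitor SPINK6 (7.22 ± 0.50), TSGA10 (6.07 ± 0.45), the calpain CAPN14 (6.05 ± 0.40), BDKRB1 (5.92 ± 0.48) and UCA1 (5.54 ± 0.85). The other largest falls were CXCL14 (-5.96 ± 0.98), PKIB (-3.74 ± 0.54), LMCD1 (-3.70 ± 0.60), the cornified envelope protein LORICRIN (-3.53 ± 0.54), the pseudokinase TRIB1 (-3.51 ± 0.42) and the protein kinase C PRKCA (-3.38 ± 0.29, other probe -0.77). For the genes named, adjusted p was at most 0.0103. Above background on all 4 senescent arrays and on 0 of 4 quiescent arrays were RUNDC3B (at least 93.3-fold), DHRS9 (at least 47.4-fold) and ABHD12B (at least 44.2-fold), each higher. The opposite held for LCN2 (at least 11.5-fold), RSPO1 (at least 9.39-fold) and HAUS5 (at least 4.10-fold), each lower, and 1 more probe of RSPO1 was above background on 2 quiescent arrays. LCN2 encodes lipocalin 2 and RSPO1 an activator of Wnt signalling. The bounded genes had adjusted p of 8.19e-06 to 0.00803. Leaving out 1 array moved MMP3 (change 7.50 without Quiescent 3), UCA1 (changes 6.29 without Quiescent 2, 4.46 without Quiescent 3) and CXCL14 (changes -6.80 without Quiescent 1, -5.13 without Quiescent 4). Also moved, but unbounded over dark arrays, were RUNDC3B (change 8.08 without Senescent 3) and LCN2 (changes -3.06 without Quiescent 3, -4.65 without Quiescent 4).

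Among genes of the secretory phenotype, 10 of 34 rose and 2 fell (11 and 2). The members had a median of 0.80 [0.80, 0.80, 0.54, 0.39], with adjusted p = 0.00691 (0.748 estimated). Of lysosome genes, 12 of 33 rose (14), with the cholesterol exporter NPC1 (2.41 ± 0.22) and the cathepsin CTSB (1.5 ± 0.20). The median of the list was 0.74 [0.74, 0.73, 0.77, 0.78], with adjusted p = 2.91e-05 (0.748 estimated). For NF-kB targets, 8 of 21 rose and 2 fell (10 and 3), with TNF (2.78 ± 0.37) after CCL2, although the other TNF probe gave -0.19. Across its members the median was 1.05 [1.05 ns, 0.84 ns, 0.83, 0.62], with adjusted p = 0.0488 (0.748 estimated). Immediate-early genes were lower, and 3 of 31 rose and 11 fell (3 and 14), among them IER3 (2.39 ± 0.34), which was higher. The list had a median of -0.73 [-0.73, -0.69, -0.85, -0.94], with adjusted p = 0.0111 (0.748 estimated). Of cholesterol synthesis genes, 1 of 24 rose and 9 fell (2 and 14), with ACAT2 (-1.77 ± 0.26) after INSIG1 and IDI1. The list median was -0.63 [-0.63, -0.64, -0.68, -0.60], with adjusted p = 2.91e-05 (0.748 estimated). For chromatin and lamina genes, 1 of 30 rose and 8 fell (1 and 8), with the HMG proteins HMGN2 (-2.18 ± 0.32), HMGB3 (-1.99 ± 0.28) and HMGB1 (-1.83 ± 0.30). Over the list the median was -0.30 [-0.30, -0.16 ns, -0.60, -0.25], with adjusted p = 0.0147 (0.748 estimated). Adjusted p was at most 0.00142 for these named genes. Processing mattered for NF-kB targets (median 0.50 with normexp, median 0.61 and 0.0558 with the mean of probes, 0.0682 with the replicate block, 0.0618 with only 2 groups fitted) and chromatin and lamina (median -0.14 with quantile scaling, median -0.18 with the mean of probes). With 1 array left out, calls or values moved for NF-kB targets (0.0616 without Control 1, 0.145 without Quiescent 1, 0.0737 without Senescent 1, 0.0521 without Control 3, 0.0607 without Quiescent 4, 0.0616 without Senescent 4) and chromatin and lamina (0.134 without Quiescent 4).

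Ribosomal protein genes were lower in senescent than in quiescent cells, and 23 of 48 fell (31), with RPL28 (-1.27 ± 0.31), RPL12 (-1.22 ± 0.32) and RPL3 (-1.15 ± 0.29). Its median change was -0.76 [-0.76, -0.96, -0.19, -0.34], with adjusted p = 1.42e-11 (0.748 estimated). Relative to the mean of the control arrays their median was -0.19, 0.09, 0.21 and 0.18 on Senescent 1 to 4. In ribosome biogenesis, 5 of 32 fell (2), with fibrillarin, encoded by FBL (-1.59 ± 0.25). The median over all measured members was -0.35 [-0.35, -0.34, -0.27, -0.16 ns], with adjusted p = 0.0103 (0.801 estimated). In oxidative phosphorylation, 2 of 36 fell (1), including the complex I subunit NDUFA10 (-1.06 ± 0.21). Their median change was -0.27 [-0.27, -0.26, -0.25, -0.16 ns], with adjusted p = 0.0215 (0.801 estimated). In the proteasome, 1 of 31 rose and 2 fell (1 and 0), with PSMD2 (1.40 ± 0.30) higher. The members had a median of -0.18 [-0.18 ns, -0.22 ns, -0.32, -0.24 ns], with adjusted p = 0.0488 (0.804 estimated). The largest adjusted p among the named genes was 0.0173. Outcomes also turned on the setting for ribosomal proteins (median -0.35 with quantile scaling), ribosome biogenesis (0.0510 with quantile scaling) and oxidative phosphorylation (0.0673 with normexp, median -0.09 and 0.385 with quantile scaling, 0.0710 with the filter on all arrays). Changes by setting were also seen for proteasome (0.139 with normexp, median -0.03 and 0.604 with quantile scaling, median -0.30 with median scaling, 0.139 with the filter on all arrays, 0.0709 with the mean of probes, 0.0649 with the replicate block). Leaving out 1 array moved calls or values of RPL12 (0.0503 without Quiescent 1, 0.0571 without Senescent 1), ribosome biogenesis (0.0892 without Quiescent 3) and oxidative phosphorylation (0.0590 without Senescent 1). The same was true of proteasome (0.0501 without Control 1, 0.0507 without Quiescent 2, 0.119 without Quiescent 3, 0.128 without Senescent 1, 0.0807 without Senescent 2, median -0.29 without Senescent 3, 0.0505 without Control 3, 0.0785 without Quiescent 4, 0.0976 without Senescent 4).

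In the panel of arrest genes, the rises were MDM2 (1.81 ± 0.34). The falls were HMGB2 (-1.58 ± 0.31), MYC (-1.46 ± 0.31), CDKN1C (-1.42 ± 0.29) and RBL1 (-0.79 ± 0.21). These calls had adjusted p of at most 0.0212. Not passing, with adjusted p, were IL1A (2.24 ± 0.84, 0.0809), E2F1 (0.76 ± 0.29, 0.0830), CDKN1A (0.90 ± 0.40, 0.134), LMNB1 (-1.08 ± 0.50, 0.152), CCNB1 (-0.71 ± 0.40, 0.242), IL6 (-0.80 ± 0.48, 0.268), RB1 (-0.46 ± 0.28, 0.286), GDF15 (1.22 ± 0.80, 0.320) and CDKN2B (-1.14 ± 0.77, 0.336). Nor did CDKN1B (-0.41 ± 0.32, 0.412), CDKN2A (0.73 ± 0.62, 0.465), CXCL8 (1.18 ± 1.06, 0.488), CCND1 (0.48 ± 0.49, 0.557), RBL2 (0.14 ± 0.21, 0.718), CCNE2 (-0.29 ± 0.57, 0.797), GLB1 (0.12 ± 0.32, 0.853) and MKI67 (-0.14 ± 0.59, 0.916) pass. Of 2 other MYC probes 1 gave 0.29. RBL1 encodes p107, a relative of the retinoblastoma protein encoded by RB1. Single arrays decided calls or values of RBL1 (0.0559 without Quiescent 1, 0.0551 without Senescent 1, 0.0714 without Senescent 2, 0.0543 without Quiescent 4), IL1A (change 3.36 and 1.36e-04 without Quiescent 3) and E2F1 (0.0221 without Quiescent 4). Also moved by 1 array were CDKN1A (0.0419 without Quiescent 2), GDF15 (changes 2.01 without Quiescent 1, 0.59 without Quiescent 4) and CDKN2A (change 0.16 without Senescent 4). Also moved by 1 array were CXCL8 (change 0.40 without Quiescent 2, change 2.47 and 0.0179 without Quiescent 3).

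A total of 19 lists did not pass, with adjusted p of 0.0656 to 0.985. Among these were integrated stress response (1 and 2 of 25, median -0.43), fatty acid synthesis (1 and 3 of 16, median -0.19), unfolded protein response (0 and 2 of 16, 0 and 0 over the list alone, 0 and 4 in limma at an unadjusted p under 0.05, median -0.36), NRF2 targets (2 and 2 of 16, median -0.39) and osteoblast lineage (0 and 3 of 9, median -0.63). Next came mitosis (0 and 3 of 39, 0 and 1 over the list alone, median -0.10), homologous recombination (3 and 0 of 20, 2 and 0 over the list alone, median 0.22), FOXO targets (4 and 4 of 23, median -0.41), extracellular matrix (0 and 2 of 27, median -0.18) and interferon response (6 and 1 of 30, median 0.18). They were followed by CDK inhibitors (0 and 2 of 7, median -0.41), DNA replication (4 and 3 of 40, 3 and 3 over the list alone, median 0.02), SRF and YAP cytoskeletal targets (3 and 1 of 24, median 0.11), autophagy (3 and 2 of 21, median 0.05) and histones (1 and 4 of 33, median 0.16). The remainder were heat shock (0 and 0 of 14, 0 and 1 in limma at an unadjusted p under 0.05, median 0.05), BCL2 family (2 and 2 of 16, median -0.03) and glycolysis and hypoxia (2 and 1 of 26, median 0.05). Passing within slide 1, with medians and adjusted p at the preset correlation, were homologous recombination (0.32, 0.0366), interferon response (0.57, 0.0470), integrated stress response (-0.66, 0.00170) and unfolded protein response (-0.58, 0.0443). Without Quiescent 1 and Quiescent 3 these were DNA replication (-0.16, 0.0439), mitosis (-0.80, 7.07e-05), histones (-0.41, 6.20e-04), extracellular matrix (-0.52, 0.00582) and osteoblast lineage (-0.73, 0.00869). With an estimated correlation and all arrays, mitosis had adjusted p = 0.922. Among the genes of these lists IFIT2 (3.40 ± 0.54), AKR1B10 (4.93 ± 0.54) and SLC2A1 (2.21 ± 0.27) were higher and CCNB2 (-2.25 ± 0.38), BCL2L11 (-2.28 ± 0.25) and RUNX2 (-2.31 ± 0.37) lower, with adjusted p of at most 0.00180. With a test pointing down, the median and mean were 0.02 and 0.01 for DNA replication, 0.16 and -0.01 for histones, 0.05 and 0.01 for heat shock, 0.05 and -0.00489 for autophagy, and -0.39 and 0.03 for NRF2 targets. The 2 heat shock genes with the largest changes were HSPB1 (-0.85 ± 0.35, adjusted p = 0.103) and HSPH1 (0.73 ± 0.34, adjusted p = 0.158). Markers of other cell types were haematopoietic markers (3 higher and 0 lower of 13, 3 and 0 over the list alone, median 0.21, adjusted p = 0.269), epithelial markers (1 higher and 0 lower of 12, 1 and 0 over the list alone, median -0.07, adjusted p = 0.998) and endothelial markers (1 higher and 0 lower of 7, 1 and 0 over the list alone, median 0.51, adjusted p = 0.269). The arrest panel had a median of -0.26. Other settings changed integrated stress response (0.0335 with the mean of probes), unfolded protein response (0.0436 with the mean of probes) and NRF2 targets (0.0481 with the filter on all arrays). Calls or values that turned on 1 array were those of integrated stress response (0.0321 without Quiescent 2, 0.0409 without Senescent 2, 0.00167 without Quiescent 4), unfolded protein response (0.0216 without Quiescent 2, 0.0236 without Quiescent 4) and osteoblast lineage (0.0483 without Quiescent 1). The same was true of mitosis (0.0429 without Quiescent 1, 0.0477 without Quiescent 3), extracellular matrix (0.0483 without Quiescent 1) and HSPB1 (0.0357 without Quiescent 3).

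In all, 2174 genes were higher and 1675 lower in senescent than in quiescent cells, 3849 of 17940 by limma. Of these, 1730 and 1071 differed at least 2-fold, and 269 and 23 at least 8-fold. The groups did not overlap for 26.8% of tested genes, where chance gives 2.86%. With slide as a block the counts were 2351 and 1774, and within slide 1 they were 1601 and 1060. Slide 2, with 1 array of each state, gives no count. Of the 29 lists 10 passed, and with an estimated correlation 0 did by camera (1 at an unadjusted p under 0.05, and 4 by fry), and 21 of the 35 splits of the 8 arrays, the real one included, shifted as many. Those below the threshold by fry were secretory phenotype, lysosome, NF-kB targets and cholesterol synthesis, but not ribosomal proteins (0.0554). The median over all genes was 0.05, or -0.07 with median scaling, 0.00 with quantile and -0.04 with normexp, and the share of calls that were higher was 56.5%, or 46.1%, 56.1% and 50.9%. Without Senescent 1 alone 1052 genes were lower, and without Senescent 2 alone 1013. Of the 73 genes named for this comparison 54 were called. With slide as a block 54 of these were called and 54 kept their direction, and within slide 1 51 and 54. Within slide 2, whose values carry no test here, 54 kept their direction.

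**Figure D2:**
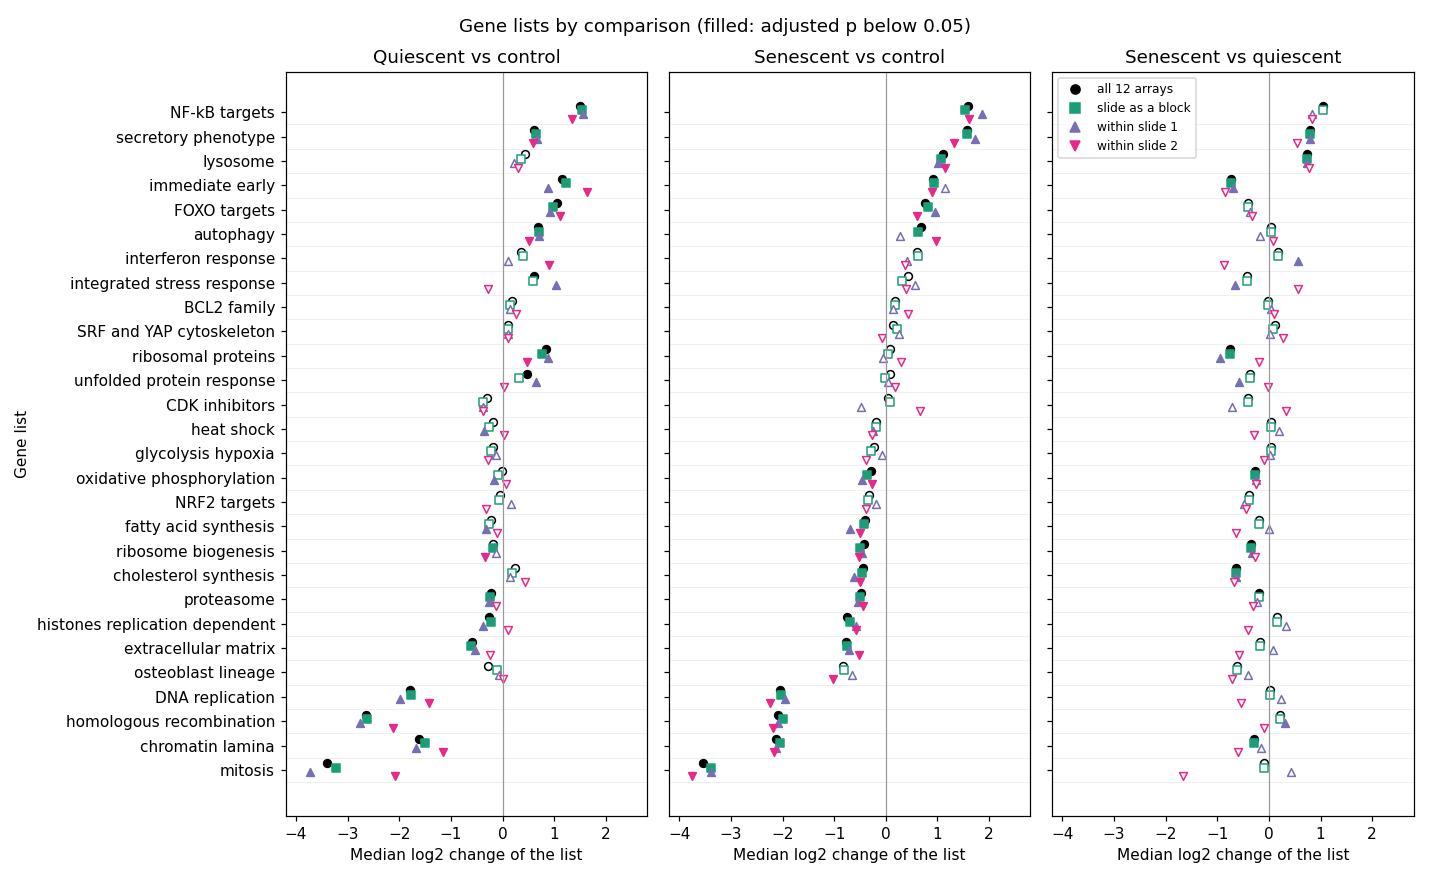
Median log2 change of the pathway lists described, in 1 panel per comparison, with all 12 arrays, with slide as a block, and within each slide. Filled points mark lists that passed with that setting, with slide 2 left untested in the last panel. Mitosis lies at -3.40 in the quiescent cells with all arrays.

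**Figure D3:**
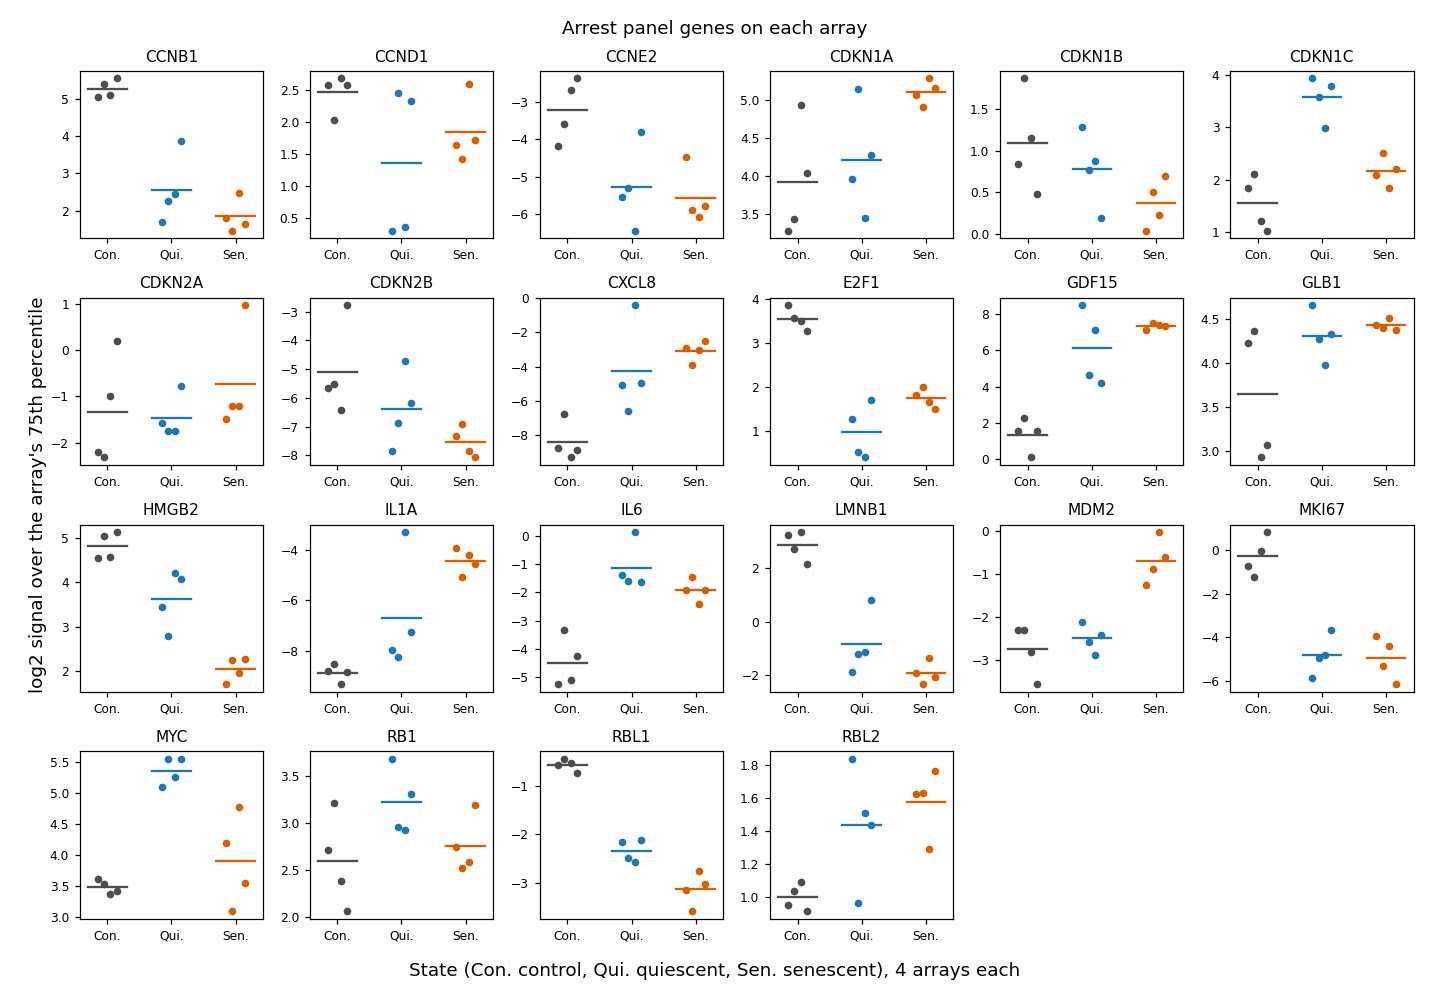
Level of the arrest panel genes on each array, as log2 signal over the 75th percentile of the array, with 1 point per array and a bar at the mean of the 4 arrays of a state. MKI67 fell by 4.53 in quiescent cells.

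Both arrests were also compared with each other gene by gene. Higher in both were 1091 genes and lower in both 943, where 403 and 212 would be called in both if the calls were independent, and 86 went opposite ways. Shared controls alone gave 0 genes in either set in 100 limma simulations, with means of 101 and 103 at an unadjusted p under 0.05. With separate controls, 2 for each arrest and so fewer arrays, 379 to 677 genes were higher in both (114 to 293 if independent) and 474 to 638 lower (63.2 to 135). Across genes Pearson r of the changes was 0.634 and Spearman rho 0.626, against r of 0.501 in these simulations and 0.403 to 0.547 with separate controls. Genes are not independent replicates, so no p is given. The covariance of the changes was 0.765, or 0.561 to 0.684 with separate controls. Of the genes higher in both, 169 were higher still in senescent than in quiescent cells, 36 were lower, and for 886 no difference was called. Of those lower in both, 91 were lower still in senescent cells, 39 were higher and 813 were not called. Within slide 1 there were 420 higher and 551 lower in both, and within slide 2 there were 32 and 68.

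**Figure D4:**
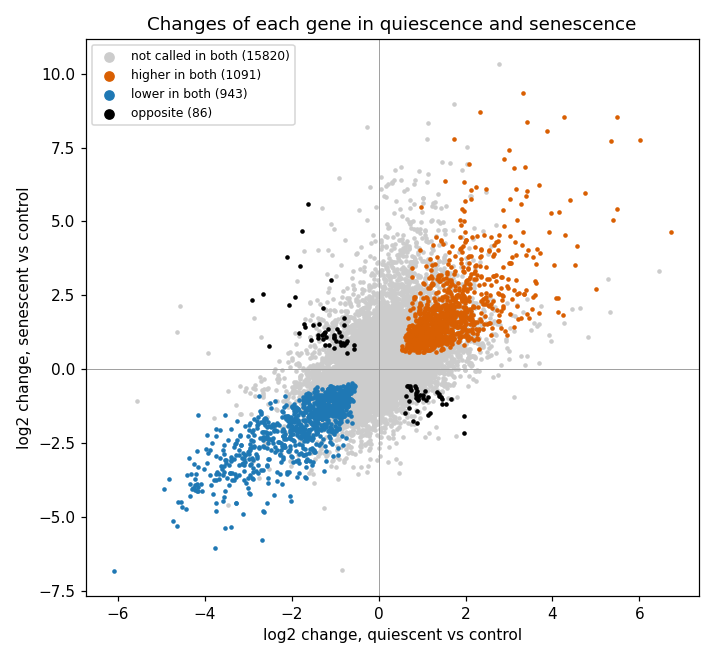
Each point is 1 of the 17940 tested genes, with its log2 change in quiescent cells on the horizontal axis and in senescent cells on the vertical axis, both against control. Genes called in both are coloured, 1091 higher in both, 943 lower in both and 86 opposite.

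**Figure D5:**
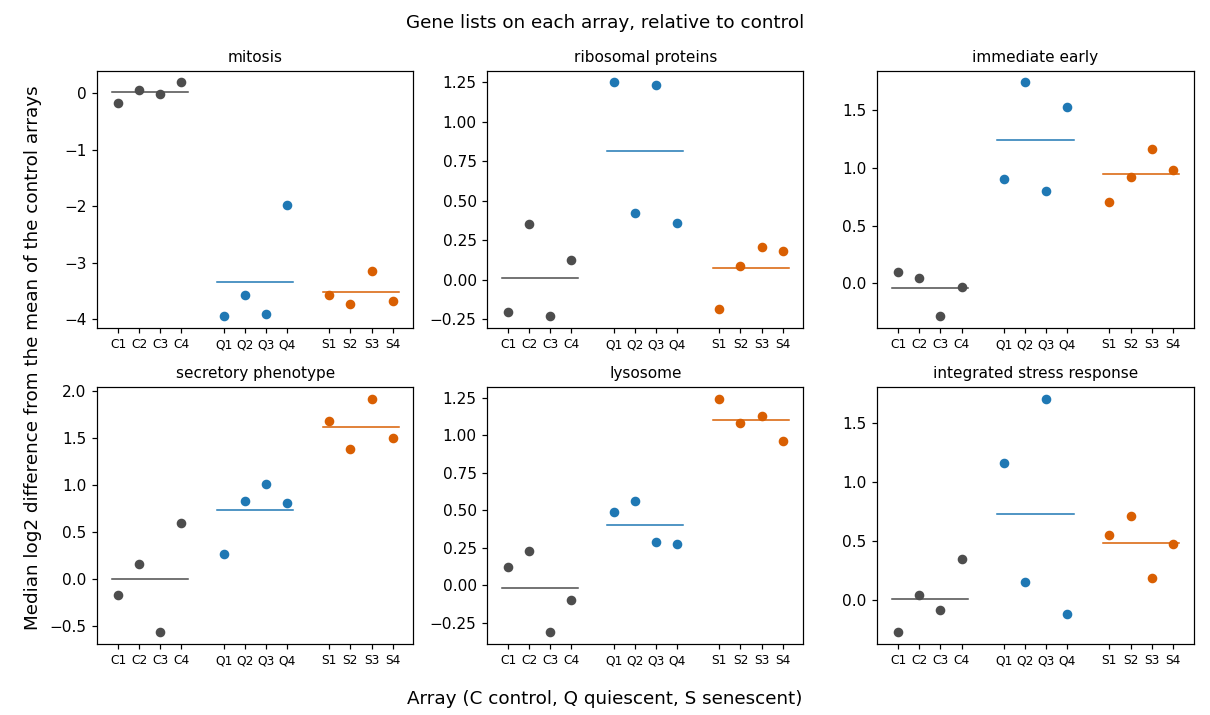
Median over the members of 6 gene lists on each of the 12 arrays, as the log2 difference from the mean of the control arrays. The ribosomal protein median lies at 1.25 and 1.23 on Quiescent 1 and Quiescent 3, and at 0.42 and 0.36 on Quiescent 2 and Quiescent 4.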

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

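All tests in this part were chosen or worded after the data were seen, except the brightness test of the ribosomal protein genes. Some values had 1 array far from the other 3 of its state, meaning that its gap to the nearest array was a large share of the whole range (Dixon's ratio for 4 samples). Among the named genes these were ABHD12B on Senescent 3 (0.848), ACAT2 on Senescent 1 (0.832), BCL6 on Quiescent 4 (0.830), CCL20 on Senescent 2 (0.870), CCND1 on Control 2 (0.847), CDKN2A on Senescent 4 (0.881), CTSB on Control 3 (0.911), DENND2D on Senescent 3 (0.892) and DUSP2 on Control 1 (0.934). Further genes were EGR1 on Quiescent 1 (0.904), EGR1 on Senescent 1 (0.864), FLRT1 on Control 4 (0.899), HTN1 on Quiescent 1 (0.850), IDI1 on Quiescent 2 (0.853), IL6 on Quiescent 3 (0.850), LCN2 on Senescent 2 (0.854), MAL2 on Control 4 (0.938) and MAL2 on Senescent 3 (0.908). The other genes were MGAT4C on Senescent 3 (0.858), MMP1 on Senescent 1 (0.894), NDUFA10 on Senescent 3 (0.867), PLAT on Control 3 (0.852), SGSH on Senescent 4 (0.874), TNF on Control 2 (0.870) and TNFAIP3 on Quiescent 3 (0.877). Among list medians they were BCL2 family on Senescent 1 (0.839), endothelial markers on Control 1 (0.869), haematopoietic markers on Control 1 (0.830) and oxidative phosphorylation on Control 2 (0.861). Chance gives about 1 in 20 groups, and 25 of 483 gene groups and 4 of 99 list groups stood out, so no array is singled out by them. Probes without a match to a gene were left out of the counts and lists of the report. Of 8608 such transcripts that could be tested, 758 were higher and 661 lower in quiescent than in control cells in limma, and 1167 and 1045 in senescent cells.

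By brightest probe, 153 genes were above background on all 4 senescent arrays and no control array (145 dark there by every probe), and 38 showed the reverse (6 with normexp). Median changes of the 153, inexact against dark control signals, were 3.96 in senescent and 0.95 in quiescent cells. Of the 153, 44 were also called higher in quiescent cells, and 8 genes were lit on all 4 quiescent arrays and no control array. A lift of dim signals was tested on Quiescent 2 and 4, since the others had the lowest shares of probes above background, 72.2% and 68.9%. These 2 arrays had 75.1% and 78.8%, against 75.3% to 79.6% on the senescent arrays, and probes above background on no array rose on them by 0.40, against 0.37 to 0.74 on pairs of senescent arrays. Of 1486 genes dark on the control arrays, 48 were lit on both, against 170 to 262 on pairs of senescent arrays, which argues against background as the whole source. The state of the cells may explain the pattern, as a hypothesis found and tested on the same data. Other differences between treated and untreated dishes were not tested.

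Ribosomal protein genes rose by a median of 0.84 on the quiescent arrays. Random lists matched on brightness had medians centred on 0.385 and up to 0.762 (list at percentile 100). Their genes were drawn singly and the members move together (estimated correlation 0.786), so a shift of bright probes stays open. With quantile scaling the median was 0.352 (matched lists at most 0.279). Low signal of Quiescent 1 and 3, where the rise was largest, cannot be told apart from a change in the cells. Without these arrays the median was 0.411 (matched lists at most 0.395), and 0 of the 23 called members passed in limma with fewer arrays (12 of the 48 at an unadjusted p under 0.05). Quiescence itself stays open and was not tested apart from signal.

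Immediate-early genes rose by a median of 1.15 on the quiescent arrays. Low signal of Quiescent 1 and 3 is argued against, since without them the median was 1.40 and 18 of 31 members rose (adjusted p = 2.56e-12 preset, 0.137 estimated with all arrays). Handling in the sort could raise such genes, and heat shock genes, which handling also raises, had a median of -0.192 with no call (lower and past the threshold with normexp, quantile and median scaling). This leaves the sort open, since the labels state one for quiescent cells only and these arrays cannot tell it from serum starvation.

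Chance was tested by splitting the same arrays in other ways. For genes called, 1 of 35 splits gave as many in each comparison. Counts were 3589 and 6000 for quiescent and senescent against control and 3849 for senescent against quiescent cells (highest others 509, 292 and 2). Mixed states widen the others' spread, so this cannot exclude chance. The split with 509 genes put Control 1, Control 3 and Control 4 with Quiescent 4, which partly follows slide 2, and with slide as a block the real counts were 2047 and 1609. For lists, 1 of 35 splits gave as many in senescent against control cells (18, others at most 17, median 7). Chance cannot be excluded for quiescent against control cells, where 3 of 35 did (16, others at most 17, median 9.5). Nor can it for senescent against quiescent cells, where 21 of 35 did (10, others at most 16, median 10.5). Of 100 splits of the 12 arrays into 3 groups, 1 gave as many genes changed in the same direction in both arrests (2034, highest other 1857). It was the real one, beside 99 drawn at random, so chance alone is unlikely there but not excluded.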

How the results depend on the processing

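The removal of Quiescent 1 and Quiescent 3 and the addition of unmatched transcripts were chosen after seeing the data, and every other alternative before the data were examined. Of the values of named genes under all alternatives, 7110 kept their call, 183 fell below the threshold, 41 newly passed and 1 reversed. Reversals count only where one side was called, and for lists by the direction of camera, not of the median. Of the list values 2589 kept their call, 127 no longer passed, 65 newly passed and 3 reversed. Of the counts and correlations 346 stayed close and 53 moved, as follows. The cause was not tested unless stated. With normexp, 3264 genes were higher in quiescent cells and 1718 in both arrests. Within slide 1, with fewer arrays, the counts higher and lower were 803 and 889 for quiescent and 2049 and 1390 for senescent cells against control, 1060 lower for senescent against quiescent, and 420 and 551 in both arrests. Within slide 2, with fewer still, they were 48 and 71, 1354 and 883, 96 and 28, and 32 and 68. Fitting only the 2 groups of a comparison, which leaves fewer arrays for the spread, gave 1102 and 1028 for quiescent against control cells. At an adjusted p under 0.01, a stricter threshold, the counts were 783 and 756, 2133 and 1424, and 1119 and 694. A fold of at least 2 left 1071 genes lower in senescent than quiescent cells. With an estimated correlation 3, 4 and 0 lists passed in the 3 comparisons. In the last, camera gave 1 at an unadjusted p under 0.05 and fry gave 4. Without Quiescent 1 and Quiescent 3, with fewer arrays, 1283 and 1039 genes were higher and lower in quiescent cells. With unmatched transcripts added, so that more features were tested, 2524 were lower in senescent than quiescent cells. With Control 1 and 2 used for the quiescent cells and the other two for the senescent cells, the correlation of both changes was 0.403 and 499 and 574 genes were higher and lower in both. With Control 3 and 4 the correlation was 0.452 and 677 were higher. With Control 1 and 3 the values were 0.481, 610 and 552, and with Control 1 and 4 they were 0.520, 442 and 504. With Control 2 and 4 the counts were 379 and 474, and with Control 2 and 3 they were 399 and 481. Leaving out 1 array at a time gave 1264 to 2469 genes higher in quiescent cells (lowest without Quiescent 1, 1273 without Control 3), 1013 to 1720 lower in senescent than quiescent cells (1052 without Senescent 1, 1013 without Senescent 2) and 666 to 1480 higher in both (666 without Control 3). With the mean of probes NUP98 reversed in senescent cells (-0.46). The integrated stress response reversed in quiescent cells within slide 2 (-0.29) and its test reversed without Quiescent 1 and Quiescent 3 (0.0481), as did the unfolded protein response (-0.18). With the replicate block the gene counts were 1797 and 1351, 3516 and 2186, and 2003 and 1336, and these numbers were not used as pairs, since correlations between arrays of one number were -0.227 to 0.467 (over 0.1 for 8 of 12) and 1 sample matched its own number best in both other groups. Background limits dim genes, since probes never above it rose by 0.72 and 0.56 in quiescent and senescent cells. Simulations with 50 or 100 genes changed per fold recovered 70%, 66% and 78% of 4-fold and 8%, 16% and 17% of 2-fold changes. Far more were called here, so these rates do not apply.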

Other observations

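Gene families grouped by the stem of their symbols were tested only after the data were seen, as was the test of chromosomal neighbours, and members were named after their values were seen. The stems also took in pseudogenes, an antisense RNA and a readthrough transcript. Alpha tubulin genes fell in both arrests, 7 of 10 in quiescent (median -1.5) and 8 of 10 in senescent cells (median -1.59), with 7 in each and 8 in each under the other 3 scalings. TUBA1A changed by -2.04 ± 0.37 and -1.84 ± 0.37 and TUBA1B by -1.25 ± 0.29 and -1.20 ± 0.29, in quiescent and senescent cells (n = 4 and 4 arrays). TUBA3C, TUBA3D and TUBA3E are near copies whose signals were not separated. Of nucleoporin genes, which build the nuclear pore, 10 of 22 fell in quiescent (median -0.56, 10 in each under the other scalings) and 13 of 22 in senescent cells (median -0.72, 13 to 15), where NUP98 rose (0.81 ± 0.18, but -0.46 with the mean of its probes). NUP210 changed by -1.65 ± 0.25 and -1.32 ± 0.25, and NUP85 by -1.60 ± 0.24 and -1.62 ± 0.24. Tetraspanins, membrane proteins of cell surfaces and vesicles, rose in senescent cells for 11 of 20 (median 1.03, 10 to 12 under the other scalings), among them TSPAN8 (4.04 ± 0.36) and TSPAN1 (3.81 ± 0.35). Lipid transporters of the ABCA family rose there for 7 of 14 (median 1.43, 0.88 with normexp, 7 to 8), with ABCA12 at 5.27 ± 0.56 and ABCA8 at 3.54 ± 0.33. Genes of the SLCO stem, mostly organic anion transporters, were higher in senescent than in quiescent cells for 6 of 11, with SLCO4C1 lower at -1.63 ± 0.40 (median 1.5, 0.34 with normexp, 4 to 6), such as SLCO2B1 (3.00 ± 0.34) and SLCO1B3 (2.56 ± 0.26). The named members had adjusted p of at most 0.0124. Of 243 families with at least 10 members, 13, 11 and 15 passed in the 3 comparisons in camera at the preset correlation, and 0 with an estimated correlation, where 14, 17 and 8 had an unadjusted p under 0.05. With it the families named had adjusted p of 0.638 and 0.625 for alpha tubulins and 0.389 and 0.512 for nucleoporins, and of 0.627, 0.570 and 0.861 for the others in the order given.

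Metallothionein genes, which bind metals, did not pass as a family in senescent cells, with 8 of 14 lower, a median of -1.40 and adjusted p = 0.0510. Their largest fall was that of MT1M (-4.46 ± 0.63, adjusted p = 2.64e-04), and close copies among them were not separated. Pregnancy-specific glycoprotein genes did not pass either, with 7 of 11 higher, a median of 2.76 (1.54 with normexp) and adjusted p = 0.0727. With 1 array left out, calls or values moved for MT1M (change -5.11 without Senescent 3).

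It was asked whether the 153 genes lit on the senescent arrays by their brightest probe are neighbours on chromosomes, as in shared domains. Leaving out pairs of one symbol stem, 1 pair were neighbours, against a mean of 1.5 in 10000 random draws from 1486 genes dark on the control arrays (highest 8, one-sided permutation p of 0.780). No excess of such pairs was seen.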
